A study of Mus musculus with 6 samples.

How the data were processed

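Total RNA from the hearts of 6 mice, 3 wild-type and 3 Txnip C247S knock-in, was isolated on silica columns and made into libraries with a NEBNext Ultra II RNA kit, per the labels' protocols. The values are whole-number read counts per gene, deposited by the authors in 1 table of 49315 Ensembl mouse genes with no normalization. The submitters' processing notes name STAR, featureCounts, Subread 1.5.2, DESeq2 and the build GRCm38.p6, with no roles. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Genes that overlap others on either strand or have near-identical copies can therefore gain or lose reads. The labels describe the samples of each genotype as hearts of different mice. They give no sex, age, litter, batch or date, nor the promoter of the recombinase.

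Columns were matched to samples by the sample descriptions. Every row named a gene, and 27660 genes had a count of 0 in all libraries. Gene names and positions came from GENCODE release M21 (GRCm38, the same assembly), which held 49056 of the 49315 identifiers. The other 259 carried 0.0070% of the counts and were kept. Library totals ran from 14146048 to 15620476, so 3 counts, taken as the floor of detection per library, equal 0.192 to 0.212 CPM. Reads carry no molecular identifiers, so counting intervals and floors cover counting error only. Counts of replicate pairs within a genotype differed by more than sampling noise (chi-square per degree of freedom 6.70 to 25.1), so each library was counted as 1 replicate. Replicate numbers follow accession order and pair no samples.

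Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by genotype, TMM normalization, glmQLFit with robust estimation and glmQLFTest on genotype, over all 6 libraries and with no covariate. Called means a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are knock-in over wild-type, their SE is the log2 fold change divided by the square root of the F statistic, and CPM are TMM-normalised. Fold changes of a gene near 0 counts in 1 genotype are given as pooled count ratios with an exact 95% binomial interval. The overall biological coefficient of variation was 14.0%.

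Before the data were examined, 48 gene lists for pathways and cell types were fixed, and 1060 of their 1061 members matched. The 43 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, beside an estimated correlation and fry. The 5 others, lymphocytes, adipocytes, skeletal muscle and lung, neural crest and Schwann cells, and sex-linked genes, had too few expressed members and 0 called genes. With an estimated correlation, camera also uses the few residual degrees of freedom of the 6 libraries. This raises p even where the estimated correlation is no higher than the preset.

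Genes named in the text follow a rule fixed at the same time. It takes Txnip, the thioredoxins and their reductases, and the 12 called genes with the largest log2 fold changes each way (mean of at least 1 CPM, groups not overlapping, no predicted genes). It adds the 5 called genes with the smallest p, and in each list up to 4 called members or the 1 with the smallest p. Other genes were chosen after their values were seen: Mlxipl, Myh7, Myom2, Tpm1, Cx3cr1, F13a1, C1qc, Etfb, Fabp3, Acaa2, Pf4, Ppbp, Gp9, Itga2b and mt-Co1 in the report, called genes outside the rule in the plot of called genes, and others in the closing section. One called gene is not reported here by name or value and is not drawn, though it stays in the counts.

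The functions were tested on simulated counts for the comparison of knock-in with wild-type, drawn from the real means, dispersions and library sizes with 200 changed genes. Of 12647 genes tested there, the fit called 12.1% of those changed by 0.5 on the log2 scale, 83.3% of those changed by 1 and 100% of those changed by 2, and 11 of 12406 unchanged genes. The 1 list shifted by 0.5 was called, with 0 of 42 others. Genes were drawn independently there, so the simulated lists held no correlation between members. It therefore does not show how often lists are wrongly called in the real data, where the estimated correlation reached 0.67 in the cytosolic ribosomal list.

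Alternatives fixed before the data were examined were RLE, upper-quartile and library-size scaling, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, no robust estimation, each library left out, mitochondrially encoded or the 20 most abundant genes left out, an adjusted p under 0.1 and a fold of at least 2. Sharing of sequence was measured as the share of 31-base words of a gene's longest transcript found, on either strand, in transcripts of other genes.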

Results

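Gene expression was measured by bulk RNA sequencing in 6 hearts of C57BL/6 mice, 3 wild-type and 3 carrying the Txnip C247S knock-in, and the deposited table held 1 column of gene counts per heart. Txnip, the thioredoxin-interacting protein, is an alpha-arrestin that binds reduced thioredoxin and restrains glucose uptake, and the knock-in replaces a cysteine that takes part in thioredoxin binding. The labels name the MerCreMer recombinase and 4-hydroxytamoxifen for both genotypes, but they do not settle whether the wild-type hearts carried the recombinase, and so whether they control for it. The total count per library lay between 14146048 and 15620476, a ratio of 1.10, and 12777 genes had enough counts to be tested. In all 6 libraries the Y-linked gene Ddx3y was counted at least 451 times and Xist had 0 counts. The question was which transcripts differ in the heart when this residue of Txnip is replaced.

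Txnip itself (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883, GRCm38) fell in the knock-in hearts, from 752 ± 35.3 to 420 ± 25.0 CPM (counts scaled to library size; SD, n = 3 per genotype). The log2 fold change was −0.84 ± 0.09 (SE; edgeR adjusted p = 0.00379), a 1.79-fold decrease, and each of the 3 knock-in values lay below each of the 3 wild-type values. An exact two-sided permutation test of the 6 CPM values gave p = 0.1, the smallest p that 3 against 3 allows. The call was lost without wild-type replicate 2 (adjusted p = 0.0525, log2 fold change −0.80) and without knock-in replicate 3 (adjusted p = 0.0642, log2 fold change −0.86). A gene count does not read the edited base, so it shows the level of the transcript and not the allele. Of the Txnip transcript's 31-base words, 19.9% also occur in other transcripts, chiefly in Gm15441 on the opposite strand.

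Among the partners of Txnip, no other member of the thioredoxin system list passed the test, out of 28 measured. Txn1, the cytosolic thioredoxin, had a log2 fold change of 0.33 ± 0.11 (SE; adjusted p = 0.346), and Txnrd1, its reductase, one of −0.36 ± 0.13 (adjusted p = 0.392). The mitochondrial pair lay nearer to 0, with −0.04 ± 0.11 for Txn2 and 0.08 ± 0.14 for Txnrd2. These last 2 changed sign when single libraries were left out. In the list of alpha-arrestins and targets of the glucose-sensing factors MondoA and ChREBP, Txnip was the only called member of 13. Mlxipl, which encodes ChREBP, had a log2 fold change of −0.74 ± 0.18 and an adjusted p of 0.0134 adjusted over the list alone, against 0.173 over all genes. The list's median was 0.09 and its mean −0.04, and camera gave an adjusted p of 0.956.

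**Figure D1:**
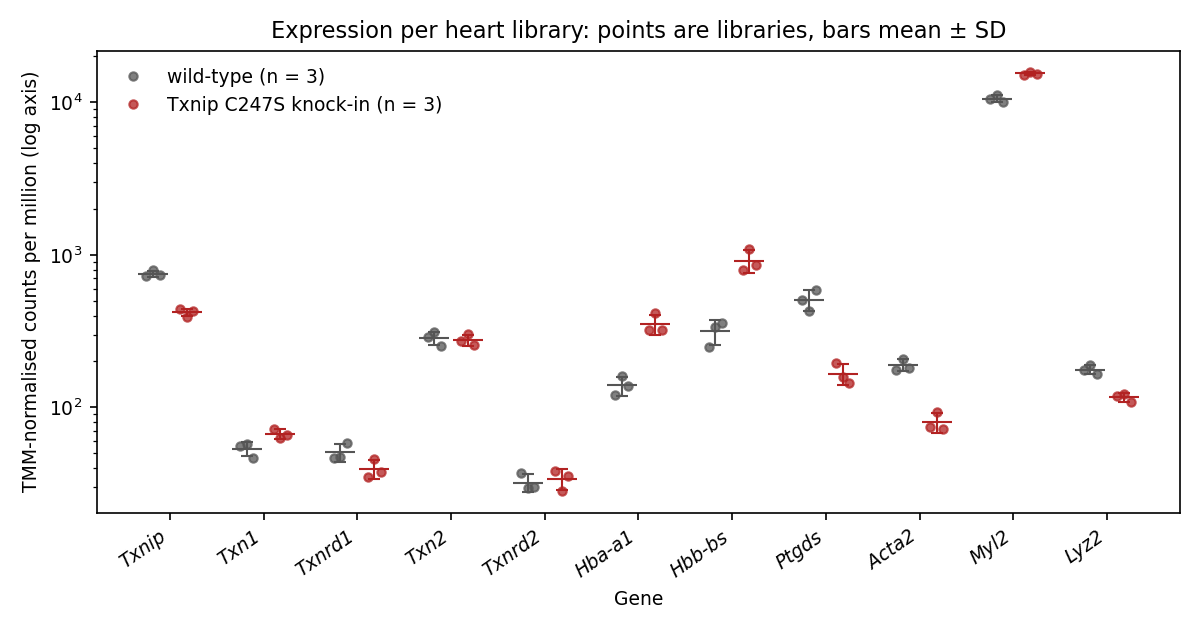
TMM-normalised CPM (log axis) of 11 genes in each of the 6 heart libraries, with points for libraries and bars for the mean ± SD of 3 wild-type and 3 knock-in hearts. Txnip fell from 752 to 420 CPM, while the values of Txn2 and Txnrd2 overlapped between the genotypes.

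Across the transcriptome, 38 of the 12777 tested genes differed between the genotypes at an adjusted p under 0.05, 14 higher and 24 lower in the knock-in hearts. Of these, 28 differed by at least 2-fold. All 38 had the 3 values of one genotype outside the range of the other, as did 16.1% of the tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 606 higher and 668 lower genes.

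**Figure D2:**
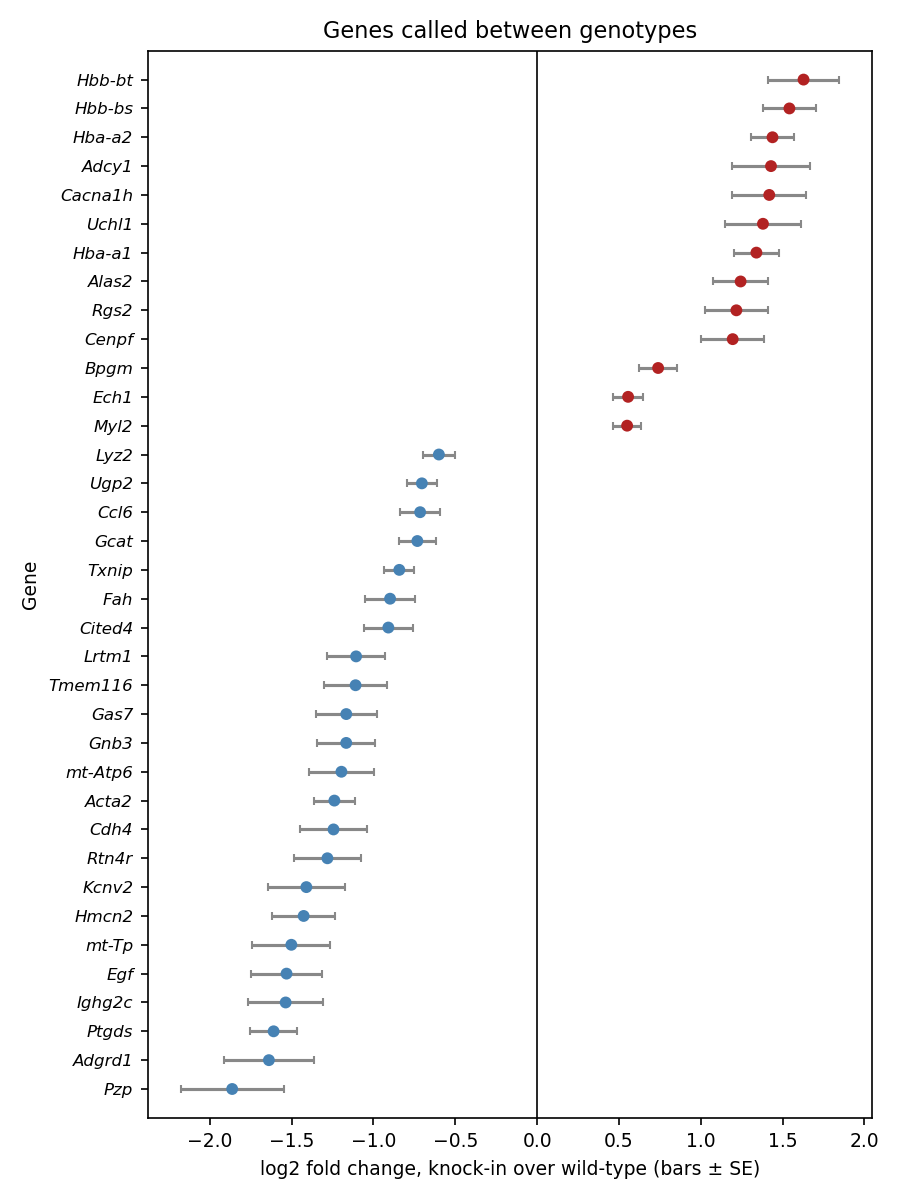
log2 fold change, knock-in over wild-type, of 36 called genes, with bars of ± SE from the edgeR fit of 3 against 3 hearts (Ifi208, near 0 counts in the knock-in hearts, is left out). The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt lay between 1.34 and 1.63, and Pzp had the lowest value drawn at −1.86.

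Genes of red blood cells rose together. In the erythroid and platelet list 7 of 13 tested members were called, all higher in the knock-in hearts, and 8 when adjusted over the list alone (camera adjusted p = 2.44e-09, but adjusted p = 0.530 with an estimated correlation). The beta-globin gene Hbb-bs rose from 315 ± 58.4 to 917 ± 159 CPM (SD, n = 3; log2 fold change 1.54 ± 0.16 SE, adjusted p = 0.00379). The alpha-globin gene Hba-a1 rose from 139 ± 19.9 to 353 ± 52.9 CPM (1.34 ± 0.14, adjusted p = 0.00268). Their close copies Hbb-bt and Hba-a2 rose by log2 values of 1.63 ± 0.22 and 1.44 ± 0.13. Because 66.9% of the 31-base words of Hbb-bs occur in Hbb-bt and 91.0% of those of Hba-a2 in Hba-a1, values within each pair are uncertain. Globin genes together took 0.138% to 0.181% of the counts in knock-in and 0.0459% to 0.0618% in wild-type libraries. Also higher were Alas2, the erythroid enzyme that starts haem synthesis (1.24 ± 0.17), and Bpgm, which makes the red-cell metabolite bisphosphoglycerate (0.74 ± 0.12). The 4 platelet members did not pass, with log2 fold changes of −0.23 ± 0.19 for Pf4, −0.42 ± 0.60 for Ppbp, 0.25 ± 0.86 for Gp9 and 0.15 ± 0.83 for Itga2b.

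Most markers of macrophages and monocytes had lower values in the knock-in hearts, though only 1 was called over all genes. Of 18 tested members 16 had a negative log2 fold change and 2 a positive one, with a median of −0.47. Camera gave an adjusted p of 2.03e-08, but 0.490 with an estimated correlation, and fry gave an adjusted p of 0.0979. Lyz2, the lysozyme of myeloid cells, was the 1 called member over all genes and fell from 177 ± 11.5 to 117 ± 7.90 CPM (log2 fold change −0.60 ± 0.10, adjusted p = 0.0399). Adjusted over the list alone, 9 members were called, all lower, among them the chemokine receptor gene Cx3cr1 (−1.17 ± 0.24), F13a1 (−0.66 ± 0.15) and the complement gene C1qc (−0.54 ± 0.13). Of the words of Lyz2, 32.8% also occur in Lyz1.

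Among genes of the heart muscle cell, Myl2, the regulatory myosin light chain of the ventricle, rose from 10525 ± 583 to 15409 ± 343 CPM (log2 fold change 0.55 ± 0.09, adjusted p = 0.0399). It was the 1 called member of 27 in the contractile and calcium-handling list and of 16 in the ventricular list. Adjusted over the list alone, 3 contractile members were called, Myl2 with Myom2 (0.73 ± 0.14) and Tpm1 (0.47 ± 0.11), and DESeq2 called 3. Neither list was called (camera adjusted p = 0.0505 and 0.122). In the cardiac ion channel list, Cacna1h, a T-type calcium channel, rose by 1.42 ± 0.23 and Kcnv2, a modifier subunit of potassium channels, fell by 1.41 on the log2 scale, while 24 of 26 members did not pass. Uchl1, a deubiquitinase, rose by 1.38 ± 0.23 and was the 1 called member of 16 in the hypertrophy and fetal programme list. Myh7, the slow myosin heavy chain of that programme, had 1.26 ± 0.30 and an adjusted p of 0.0304 adjusted over the list alone, against 0.216 over all genes. The signalling genes Rgs2 (1.22 ± 0.19) and Adcy1 (1.43 ± 0.24) also rose.

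The gene with the smallest p among those that fell was Ptgds (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046), a prostaglandin D2 synthase, at 508 ± 78.8 against 166 ± 26.8 CPM (log2 fold change −1.61 ± 0.14, adjusted p = 0.00222). Acta2, smooth-muscle actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), fell from 189 ± 17.1 to 80.1 ± 11.8 CPM (−1.24 ± 0.12, adjusted p = 0.00268). It was the 1 called member of 16 in the smooth muscle and pericyte list, whose median was −0.06. Ugp2, which makes the UDP-glucose used for glycogen, fell by 0.70 on the log2 scale (SE 0.09, adjusted p = 0.0143) and was the 1 called member of 24 in the glycogen list. Further falls were seen for Hmcn2 (−1.43), the growth factor gene Egf (−1.53), the immunoglobulin constant gene Ighg2c (−1.54), Adgrd1 (−1.64) and Pzp (−1.86). Rtn4r (−1.28) and the cadherin gene Cdh4 (−1.24) fell as well. Ifi208, an interferon-inducible gene on chromosome 1, had 25, 33 and 33 counts in the wild-type and 1, 0 and 0 in the knock-in hearts. The pooled ratio, wild-type over knock-in, was 97.2 (95% exact counting interval 17.0 to 3879), and 43.1% of the gene's words occur in other genes, chiefly Ifi213.

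Of 44 cytosolic ribosomal protein genes 42 had positive log2 fold changes with a median of 0.26 (camera adjusted p = 2.26e-15, but adjusted p = 0.752 with an estimated correlation). None was called over all genes by edgeR, but 30 were higher at an unadjusted p under 0.05, 23 were called when adjusted over the list alone and 3 were by DESeq2. The level of this list was lowest in wild-type replicate 3, at −0.28 against −0.07 and −0.03 in the other wild-type hearts, and without that library the median was 0.19. Rpl13a, the member with the smallest p, stood at 100.3 ± 0.825 and 137 ± 4.46 CPM. The nuclear-encoded respiratory chain had a median of 0.14, with 40 of 50 members positive and 0 called by edgeR or DESeq2, 17 being higher at an unadjusted p under 0.05 (camera adjusted p = 3.02e-06, adjusted p = 0.793 with an estimated correlation). The respiratory chain level was lowest in wild-type replicate 3, at −0.19 against −0.0077 and −0.0041 in the other wild-type hearts and 0.02 to 0.13 in the knock-in hearts (mean log2 CPM relative to all 6 libraries). Without that library the median was 0.098 (camera adjusted p = 0.0228). Fatty acid uptake and oxidation had a median of 0.16 and 28 of 36 members positive, with 0 called by edgeR, 3 by DESeq2 and 6 at an unadjusted p under 0.05 (camera adjusted p = 2.58e-04, adjusted p = 0.752 with an estimated correlation). Its members Decr1 (0.48 ± 0.09), Etfb (0.47 ± 0.09), Fabp3 (0.55 ± 0.11) and Acaa2 (0.34 ± 0.09) were the 4 called when adjusted over the list alone.

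Most genes encoded in mitochondrial DNA had negative log2 fold changes, 10 of 13 members, with a median of −0.41 (camera adjusted p = 2.58e-05, adjusted p = 0.335 with an estimated correlation, and adjusted p = 0.00275 in the fry test). The estimated correlation of this list was −0.071, below the preset 0.01. A higher correlation between members therefore does not account for the larger camera p, which unadjusted was 3.00e-06 with the preset and 0.00779 with the estimate. The estimated setting also uses fewer degrees of freedom, which raises p. One member was called, mt-Atp6, at 69.3 ± 18.4 against 30.3 ± 4.49 CPM (log2 fold change −1.20 ± 0.20, adjusted p = 0.0456), and 7 were when adjusted over the list alone. Nearly all of its sequence, 99.5% of the words, also occurs in Gm10925, a nuclear copy on chromosome 1, so its value is uncertain. The most abundant member, mt-Co1, had −0.05 ± 0.10 and took 10.9% to 13.2% of all counts per library. The counts of mt-Atp6 were very small beside these. How many of its reads were dropped or placed elsewhere was not measured. In a split chosen after the values were seen, the 5 members sharing at least 95% of their words with other transcripts had a median of −0.94. The 8 other members had a median of −0.14. The transfer RNA gene mt-Tp, outside the list, fell from 4.96 ± 1.05 to 1.75 ± 0.199 CPM. Wild-type replicate 3 had the highest mitochondrial share of counts, 28.0%, against 22.9% to 24.3% in the other libraries.

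The cell cycle list was called higher (camera adjusted p = 2.58e-04, adjusted p = 0.752 with an estimated correlation), with 23 of 26 members positive. Cenpf, a kinetochore protein, was its 1 called member (log2 fold change 1.20 ± 0.19). The glucocorticoid-responsive list was called higher too (camera adjusted p = 0.00959, adjusted p = 0.793 with an estimated correlation), but its 1 called member, Ptgds, fell. Both list calls were lost without wild-type replicate 3 (camera adjusted p = 0.0599 and 0.291) and without knock-in replicate 1 (0.0874 and 0.212). The glucocorticoid median of 0.33 became 0.16 without wild-type replicate 3, 0.20 without knock-in replicate 1 and 0.58 without knock-in replicate 2, and the cell cycle median of 0.34 became 0.17 without knock-in replicate 1.

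**Figure D3:**
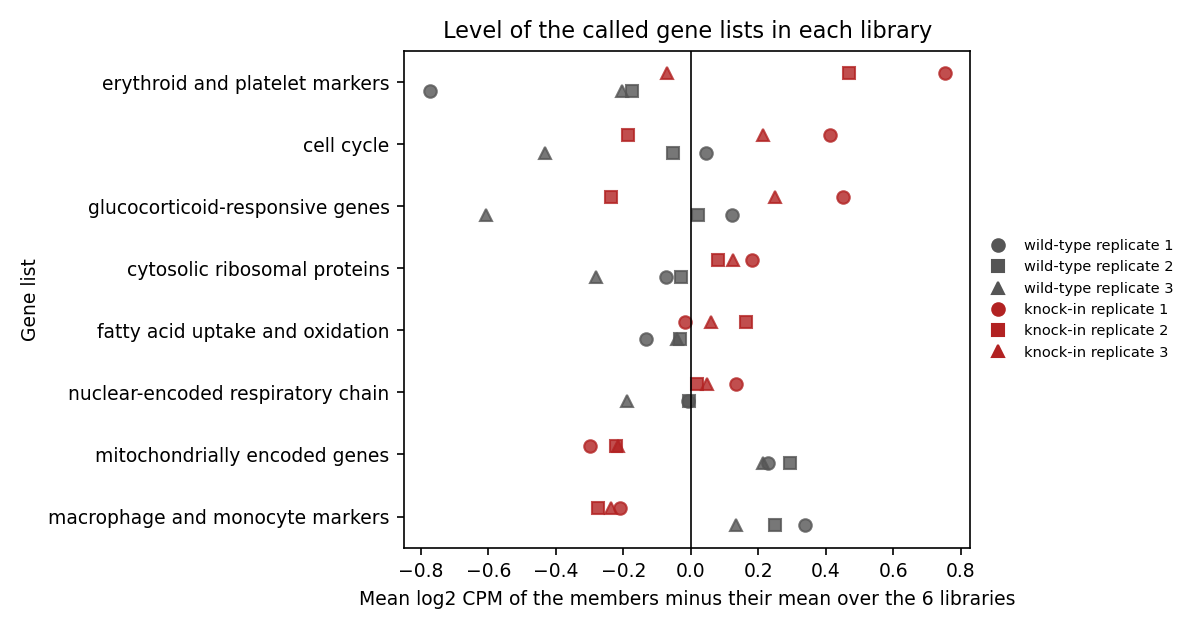
Mean log2 CPM of the members of the 8 called gene lists, relative to their mean over the 6 heart libraries, with 1 symbol per library. The macrophage and mitochondrially encoded lists lay above 0 in each wild-type and below 0 in each knock-in library. The cytosolic ribosomal and respiratory chain lists lay the other way in each library. In the fatty acid and erythroid lists the genotypes did not overlap, while in the cell cycle and glucocorticoid lists they did.

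The other 35 tested lists were not called by camera, with adjusted p from 0.0505 to 0.956. Among them were glycolysis, the TCA cycle, NRF2 targets, the inflammasome, interferon-stimulated genes, fibrosis, hypoxia, endothelial cells and fibroblasts, each with 0 members called by edgeR. Of the 213 genes in these 9 lists, 29 had an unadjusted p under 0.05 and 3 were called by DESeq2. The 21 tested neighbours of Txnip on chromosome 3 had 0 members called by edgeR or DESeq2, 2 at an unadjusted p under 0.05 and a median of 0.05. Single members that did not pass over all genes are given as values, some of which passed when adjusted over the list alone. S100a9, a neutrophil gene, had a log2 fold change of 1.68 ± 0.33 (adjusted p = 0.0897, list alone 0.00371 among neutrophil and 0.00603 among inflammatory genes). Pcx, pyruvate carboxylase, had −0.61 ± 0.12 (adjusted p = 0.0883, list alone 0.0142). Hmox1, an NRF2 target, had −0.58 ± 0.17 (adjusted p = 0.254) and Comp, a matrix protein, 1.37 ± 0.32 (adjusted p = 0.146, list alone 0.0260). The fibrosis list had 4 calls adjusted over the list alone, 2 higher and 2 lower. Cidea, a lipid droplet protein from the adipocyte list, which had too few members for a test, stood at 0.62 ± 0.11 (adjusted p = 0.0667). In 9 of the 35 lists the median, mean and camera direction differed in sign.

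The number of called genes depended on single hearts. It was 14, 5 and 13 without wild-type replicate 1, 2 or 3, and 28, 174 and 6 without knock-in replicate 1, 2 or 3. In each of these 6 fits Acta2, Hba-a1, Hba-a2, Ifi208 and Ptgds were called. By contrast, 15 of the 38 genes were called in 1 of the 6 fits, that without knock-in replicate 2, which called all 38. Among them were Lyz2, Myl2, Uchl1, Kcnv2, Adcy1, Pzp, Bpgm and mt-Tp. A further 9 were called in 2 of the 6, among them Hmcn2, Ighg2c, Rtn4r, Adgrd1, Cdh4, Cacna1h, Cenpf and mt-Atp6. With an estimated correlation between genes camera called 0 of the 43 lists, with 4 at an unadjusted p under 0.05, and fry called 1. That camera setting also uses fewer degrees of freedom, so the loss of calls does not measure correlation alone. At the preset correlation, each of the 10 splits of the 6 libraries into 3 and 3 called at least 8 lists. The count of 8 called lists is therefore not particular to genotype.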

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

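Corrections for transcript length and GC content, the covariates and the use of 4 libraries were chosen after seeing the data. All 38 called genes kept their direction under each alternative that tested them. Scaling, robustness, the stricter filter and leaving out mitochondrial or abundant genes gave 36 to 40 calls. Without a filter there were 317 (144 higher, 173 lower), with DESeq2 138 (66 and 72, all 38 among them), with limma-voom 18 (7 and 11) and at an adjusted p under 0.1 75 (28 and 47). Removing the GC trend gave 51, 24 of them higher. The mitochondrial share as a covariate gave 14 (5 and 9), 12 of them among the 38. A covariate made from the first residual component, which is optimistic because it comes from the same counts, gave 697 (320 and 377). The 4 libraries without wild-type replicate 3 and knock-in replicate 2 gave 392 (171 and 221). The median prior degrees of freedom, 6.89 with all libraries, became infinite without a filter, 11.4 without knock-in replicate 2 and 5.98 without wild-type replicate 2; the cause of the moves was not tested.

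Leaving out 1 library gave 5 (without wild-type replicate 2) to 174 calls (without knock-in replicate 2), 2 to 88 higher and 3 to 86 lower. Txnip then ranged from −0.87 to −0.78 on the log2 scale. Its call was lost without wild-type replicate 2 (−0.80) and knock-in replicate 3 (−0.86), where fewer samples were tested; the adjusted p over all its alternatives ran from 9.76e-12 to 0.0642. Txnrd2 ranged from −0.0045 (without knock-in replicate 1, a turned sign) to 0.209. Txn2 ranged from −0.115 to 0.028 (without wild-type replicate 2), and its sign also turned without knock-in replicate 3 (0.013). Of 606 values of the 29 called named genes under alternatives, 134 lost the call, and of 776 values of the 37 not called, 64 gained one. Lists called numbered 0 with an estimated correlation, 1 by fry, 14 with 4 libraries, and 8 to 14 with 1 library left out, the highest without knock-in replicate 2.

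Of the 10 splits of the 6 libraries into 3 and 3, 2 called at least as many genes as the 38 of the genotypes, and the highest other called 173. All 10 called at least 8 lists, the number called between the genotypes, and the highest other called 14. The number of called lists therefore did not set the genotypes apart from other groupings of the libraries. For the number of genes, no share under 0.05 can be reached with 10 splits. The split with 173 calls, wild-type replicate 1 with knock-in replicates 1 and 3 against the rest, points to a structure of the samples beside genotype. The first principal component (37.4% of the variance) separated the same libraries, and the second (27.0%) the genotypes. Sex was not run as a covariate because each library had Y-linked counts and 0 of Xist. Small changes were mostly missed at this depth, spread and number of libraries, which were not varied: in simulation 12.1% of genes changed by 0.5 on the log2 scale were called.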

Other observations

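The tests of the explanations for Txnip, the red-cell genes and the mitochondrially encoded list were chosen after the results were seen, although the scalings and the list tests they draw on had been fixed before. Beyond the lists, 3 genes had at least 8 counts in each wild-type and at most 1 in each knock-in heart: Ifi208, Lrtm2 (8, 18 and 9 against 0 in each) and Tspan10 (8, 13 and 11 against 0, 1 and 0). None did so in reverse, nor in the 18 other choices of 3 libraries. The cutoffs of 8 and 1 were not among the rules fixed beforehand, and the lowest wild-type counts of Lrtm2 and Tspan10 lie on the first. The comparison with other choices of libraries therefore gives little support. For Lrtm2 the exact 95% lower limit of the pooled ratio, wild-type over knock-in, was 9.60. The neighbours of Ifi208, Ifi207 and Mndal, had log2 fold changes of 0.06 ± 0.29 and 0.03 ± 0.21.

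Some genes outside the rule were called. Lrtm1, a leucine-rich repeat membrane protein, fell by 1.11 on the log2 scale (SE 0.18), the macrophage chemokine gene Ccl6 by 0.71 (SE 0.12) and Gnb3 by 1.17 (SE 0.18), while Ech1, an auxiliary enzyme of fatty acid oxidation, rose by 0.56 ± 0.09. Among single libraries, Wdfy1 was at 1.84 CPM in wild-type replicate 1 against 10.01 to 21.2 in the others. Per1 was at 9.69 CPM in wild-type replicate 3 against 36.2 to 48.0 in the others, and Gm4841 reached 13.97 CPM in knock-in replicate 2.

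Txnip was lower in the knock-in hearts. A fall in expression across the surrounding locus is argued against by the 21 tested neighbours, whose median log2 fold change was 0.045 (SD 0.28) against −0.84 for Txnip. Lower activity of MondoA or ChREBP cannot be told apart from an effect on Txnip alone. Arrdc4, another target, had 0.20 ± 0.19, and the list of alpha-arrestins and targets had a median of 0.09 with 8 members positive and 5 negative. Mlxipl, which encodes ChREBP itself and so is not a plain measure of its activity, had −0.74 ± 0.18. An effect of the edited allele on its own transcript stays open and was not tested.

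Red-cell genes were higher in the knock-in hearts. Scaling is argued against, since the smallest globin log2 fold change under any scaling was 1.30, above the 0.14 that separates the highest from the lowest total. Reads moved between globin copies would leave their sum in place, but the mean share of all globin counts was 2.74 times that of wild-type. More whole blood left in these hearts, with platelets in proportion, cannot be told apart from an effect of genotype on red cells, which was not tested: 2 of the 4 platelet members, Pf4 and Ppbp, lay below the red-cell median of 1.34 by over 2 SE, but Gp9 and Itga2b were too poorly measured. Neutrophil genes went both ways, with S100a9 (1.68 ± 0.33), Retnlg (2.28 ± 0.62) and S100a8 (1.23 ± 0.44) near or above that median, Mmp9 (0.40 ± 0.35) and Csf3r (−0.06 ± 0.40) below it by over 2 SE, and their list not called (camera adjusted p = 0.119).

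The mitochondrially encoded list was lower in the knock-in hearts. A general fall is argued against by the 8 members that share under 95% of their words with other transcripts, whose median was −0.14 against −0.94 (SD 0.23) for the 5 others. Between these sets of genes, which are not independent, an exact two-sided permutation test gave p = 0.00544. The falls were on average larger in the members with near-identical nuclear sequence. Reads limited or misplaced by such sequence would be so in both genotypes, so this comparison of genes cannot say why the genotypes differ. The members mt-Atp8 (−1.03, 7.5% shared) and mt-Nd6 (−0.41, 7.4%) fell with little measured sharing, as did mt-Tp (log2 fold change −1.501, 0.0%) outside the list. Sharing was measured against annotated transcripts only, so a low share does not show that no nuclear copy exists. Either member may therefore stand in the wrong set. The copies of mt-Atp6 and mt-Co2, Gm10925 and Gm28661, lie at 24613974 to 24614651 and 24614885 to 24615565 on chromosome 1. The stretch between them holds none of the 7 annotated copies, and mt-Atp8 overlaps mt-Atp6. The value of mt-Atp8 is therefore weak evidence of a fall without near-identical nuclear sequence. A plain move of reads to the nuclear copies is argued against, since the 7 annotated copies on chromosome 1 had a median of −0.47 (SD 0.21). An effect of genotype on these transcripts stays open.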
